A study of Mus musculus with 6 samples.

How the data were processed

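Transcripts were measured in 6 input libraries of an m6A sequencing assay, 3 from mouse BMSCs given AAV with the WT form of FTO and 3 given the 3KR form. An input library is sequenced without the immunoprecipitation step that enriches m6A. Total RNA was extracted with TRIzol and poly(A) RNA was selected on oligo(dT) beads, per the labels' protocols. The immunoprecipitated libraries were not analysed here.

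The deposited table gave one value per gene and library in FPKM (fragments scaled by transcript length and by the mapped fragments of the library), per the file headers. The aligner, the quantifier and the gene annotation are not given in the sources used here. The only build named is GRCh38, per the submitters' processing notes, which is a human assembly, while the organism label and the gene symbols are mouse. For this reason no coordinates are given. A reference table of mouse genes on assembly GRCm38.p6 was used for names alone, and 98.7% of the tested names matched its symbols or synonyms. FPKM divides by the fragments of the library, so a gene that takes a larger share lowers the values of the rest, and no normalization between libraries is stated.

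The table had 19763 rows, of which 24 repeated a gene name. The row with the highest mean was kept for each name, leaving 19739 genes, of which 713 were at 0 in each library. Whole-read steps were searched among genes under 2 FPKM in pairs of libraries. The most frequent ratio of values was shared by at most 14 of 5783 genes, so no read counts could be recovered and the depth is unknown. No interval or detection limit that needs the depth is therefore given.

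Samples were grouped by the form of FTO in their titles. Genes with an FPKM of 1 or more in at least 3 of the 6 libraries were tested, 10985 in all. Values were taken as log2(FPKM + 1) and compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A log2 fold change is 3KR minus WT on this scale, which understates the change of genes with a low FPKM. Ratios are of mean FPKM as deposited. The median fold change of all tested genes was subtracted where a change is called relative, while p-values test the change on the deposited scale unless another scaling is named. Directions were checked under 4 scalings: as deposited, each library rescaled to the same sum, median ratio scaling over the tested genes, and quantile normalization.

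The 36 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members, 29 of them, were compared with the other genes by camera in limma, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera was repeated with the correlation estimated for each list, and fry was run as another test. The genes named were the 12 with the largest positive and the 12 with the largest negative log2 fold change among those with an adjusted p under 0.05 and groups that did not overlap, then Fto, then up to 4 members of each tested list with the smallest p. Model names without a gene symbol were passed over, 1 among the leading higher genes. The distance between libraries and the level of Fto were compared by exact permutation tests.

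The fit was tested on simulated data for the comparison of 3KR with WT, with the means and spread of the 10985 tested genes and 200 changed genes in each of 5 runs. It called 3.6% of genes changed 1.1-fold, 48% of those changed 1.25-fold, 83.2% of those changed 1.5-fold and 96.8% of those changed 2-fold. With 200 changed genes the adjustment is stricter than in the data, where 6662 genes were called. These shares therefore do not give the sensitivity of the real comparison. It called 25 of 53925 unchanged genes and 0 of 145 lists. A shift of the adipocyte list by 0.3 was called in 5 of 5 runs. The simulated genes varied independently, while the correlation estimated in the data was 0.57 for the interferon list, for example. The simulated list results therefore do not give camera's error or power in the data.

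Alternatives were another pseudocount, other filters, the 3 other scalings, a replicate block, library weights, no intensity trend, the 2 other list tests and leaving out each library in turn. A test of a minimum fold of 1.5 (limma's treat) was added after seeing the data.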

Results

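The series measured transcripts in primary mouse bone marrow mesenchymal stromal cells (BMSCs), the marrow cells that can form bone, fat and cartilage cells. The cells had received an adeno-associated virus (AAV) carrying FTO, an enzyme that removes the N6-methyladenosine (m6A) mark from RNA, either as the form labelled WT or as the form labelled 3KR. The series title concerns SUMOylation of FTO, the attachment of a small SUMO protein, and the differentiation of BMSCs in bone loss that accompanies inflammatory bowel disease. The labels do not spell out 3KR. The 6 libraries analysed here were input libraries of an m6A sequencing assay on poly(A) RNA, 3 per form, and they give transcript levels, not m6A. Cells without the virus were not analysed here, so every comparison is of the 3KR form with the WT form. The values were FPKM with no read counts, so the depth of each library is unknown. The FPKM of a library summed to between 390527 and 391767 in the WT group and between 408605 and 421234 in the 3KR group. Vim, which encodes the intermediate filament vimentin, took the largest share in each library, 4.95% to 5.14% of the sum in WT and 8.27% to 8.71% in 3KR.

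Both vectors carry Fto, so its level does not check which form a library received. Fto was abundant in both groups, ranking 128th by mean FPKM, at 258 ± 9.84 FPKM in WT and 443 ± 24.8 in 3KR (SD, n = 3 each). It was 1.71-fold higher in 3KR on the deposited scale, with a log2 difference of 0.77 (limma adjusted p = 4.497e-06). Relative to the median gene it was 1.54-fold higher, a log2 difference of 0.62. After median ratio scaling the log2 difference of Fto was 0.60 (limma adjusted p = 8.356e-06). It was called higher in 3KR under all 4 scalings tried. The lowest 3KR library, at 422 FPKM, lay above the highest WT library, at 269. The exact permutation test of the 3 against 3 libraries gave p = 0.1, two-sided, which is the smallest p that 10 splits allow. The FPKM of Fto does not separate vector from endogenous transcripts, and the form of FTO and the level of its transcript changed together between the groups.

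The first comparison asked how far the transcriptome of 3KR cells differed from that of WT cells. Libraries of one group correlated at a Spearman rho across genes of 0.9939 to 0.9949, and libraries of different groups at 0.9608 to 0.9628. The mean distance, 1 minus rho, was 0.0326 larger between than within groups (exact permutation p = 0.1, the smallest possible). Of 10985 genes tested, 6662 differed at a limma adjusted p under 0.05, or 60.7%. The median gene was 0.15 higher in 3KR on the log2 scale, a ratio of 1.11, so changes below are given relative to it unless a level or a ratio of FPKM is named. This shift weighed on the split by direction. On the deposited scale 5127 genes were higher and 1535 lower in 3KR, and after median ratio scaling 2371 were higher and 2645 lower. Rescaling each library to the same sum gave 3674 higher and 1987 lower, and quantile normalization gave 3142 higher and 2190 lower. Under all 4 scalings, 2366 genes were called higher and 1525 lower. The 3 other scalings lower 3KR against the deposited scale, so a gene called lower as deposited is nearly bound to stay so. Of the 1535 lower genes 1525 did, against 2366 of the 5127 higher ones. A call under all 4 scalings thus adds little for genes that fell. On the deposited scale the groups did not overlap for 7330 genes, or 66.7%, where chance gives 10% if nothing differs. The shift of 0.15 exceeds the median within-group SD of 0.0723, so it can separate genes by itself. The overlap was not counted under the other scalings. At 2-fold or more on the log2(FPKM + 1) scale, 174 genes were higher and 287 lower as deposited, 117 and 360 after median ratio scaling, 207 and 395 after rescaling to the same sum, and 133 and 323 after quantile normalization. With a pseudocount of 0.1 in place of 1 the counts were 339 and 383. The labels do not say that the 3 libraries of a group came from separate mice or cultures, so the p-values measure only the spread between these libraries, which may be technical.

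The 12 genes with the largest drop in 3KR included genes of acute-phase, complement and antimicrobial proteins. Saa3, an acute-phase serum amyloid, fell from 553 ± 25.9 to 21.8 ± 2.90 FPKM (SD, n = 3), a 25.4-fold lower level and a relative log2 change of -4.76. Cfb, complement factor B, fell from 34.0 ± 2.16 to 1.31 ± 0.147 FPKM, and C3, the central complement component, from 267 ± 28.6 to 30.7 ± 1.23. Hp, which encodes the haemoglobin-binding protein haptoglobin, was 13.2-fold lower. Lcn2, encoding the iron-siderophore-binding lipocalin 2, was 11.5-fold lower, and Cxcl5, a neutrophil-attracting chemokine, 11.3-fold lower. The others of the 12 leading genes were Scara5, Mfap4, Vnn3, Fmo1, Ptgds and Lgr5, with relative log2 changes from -3.65 (Scara5) to -3.14 (Lgr5). Lgr5 is a receptor for R-spondins, which enhance Wnt signalling. All 12 were called lower under all 4 scalings, which adds little for genes that fell, as given above.

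The genes with the largest rise in 3KR included regulators of skeletal cells. Sp7, the osteoblast transcription factor osterix, rose from 2.09 ± 0.121 to 24.9 ± 0.559 FPKM (SD, n = 3), an 11.9-fold higher level and a relative log2 change of 2.91. Cyp26b1, a retinoic acid-degrading enzyme, rose from 1.105 ± 0.0782 to 19.1 ± 1.29 FPKM, and Fgfr3, a fibroblast growth factor receptor of the growth plate, from 0.622 ± 0.0747 to 11.9 ± 0.888. Id1, a target of bone morphogenetic protein (BMP) signalling, rose 5.90-fold to 111 ± 17.2 FPKM. Notum, an extracellular Wnt inhibitor, rose 8.39-fold, and Fzd9, a Frizzled receptor for Wnt, rose to 5.43 ± 0.407 FPKM from 0.166 ± 0.0539. Pcp4l1 rose most on the log2(FPKM + 1) scale, by 3.33 relative to the median gene, and Lor, Serpinb2, Sv2c, Dynap and Gldn completed the 12. All 12 were called higher under all 4 scalings. The log2 scale with a pseudocount understates the change of genes with a low FPKM.

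**Figure D1:**
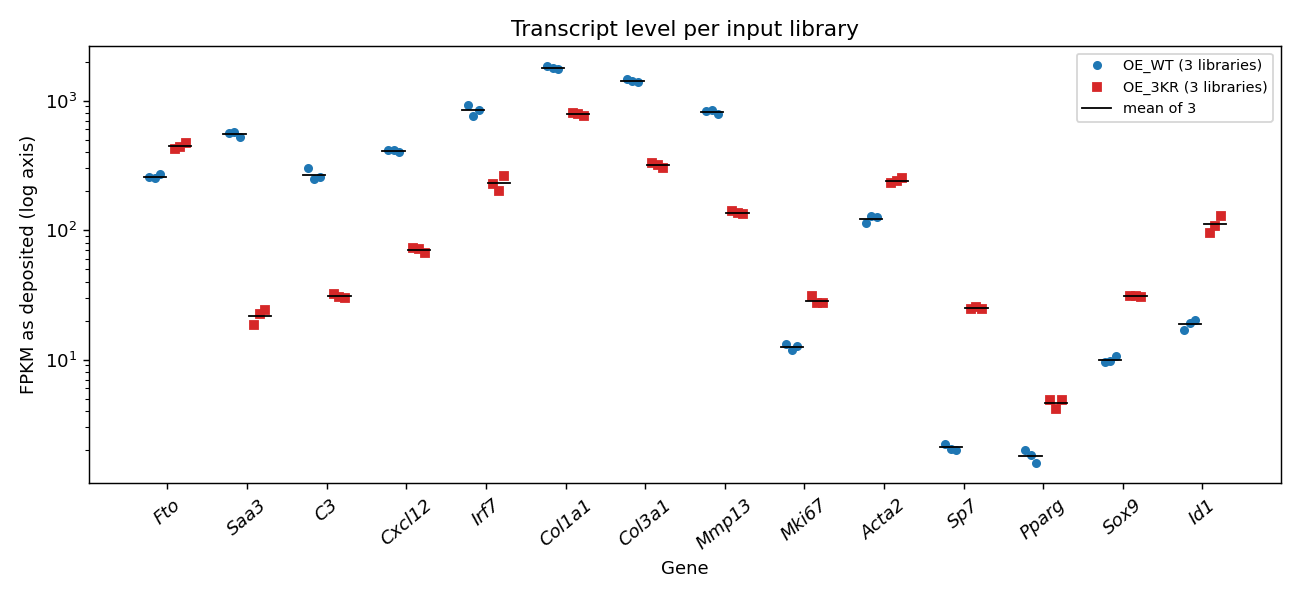
FPKM as deposited, on a log axis, of 14 genes in the 3 WT libraries (circles) and the 3 libraries of 3KR (squares), with black lines at the group means. The groups do not overlap for any gene drawn: Saa3 lay near 553 FPKM in WT and 21.8 in 3KR, Col1a1 near 1785 and 787, and Sp7 near 2.09 and 24.9.

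The next comparisons asked which of 36 gene lists, fixed before the data were examined, differed between the forms. The lists cover the lineages of BMSCs, other marrow cells, signalling, stress and the m6A and SUMO machinery. Of the 29 lists with enough tested members, camera with its preset correlation called 12 at an adjusted p under 0.05, 9 of them lower and 3 higher in 3KR. None of the 12 was called with an estimated correlation, where their adjusted p ran from 0.107 to 0.248. That setting also tests on the 4 residual degrees of freedom of the fit, so a lost call need not reflect correlation between genes. The G2 and M phase list had an estimated correlation of 2.8e-04, under the preset 0.01. Its unadjusted camera p still went from 3.676e-08 to 0.003676. The counts of members adjusted over the list alone equalled the counts over all genes tested in 22 lists, and they are given for the other 7.

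Interferon-response and inflammatory transcripts were lower in 3KR. All 21 tested members of the interferon list fell, under all 4 scalings, with a median relative log2 change of -1.87 (camera adjusted p = 3.509e-22, adjusted p = 0.182 with an estimated correlation). Zbp1, a sensor of Z-form nucleic acid, fell from 18.7 ± 1.68 to 1.84 ± 0.392 FPKM (SD, n = 3). Iigp1 and Gbp3, interferon-induced GTPases, fell from 39.5 ± 3.93 to 8.51 ± 0.272 and from 16.7 ± 0.572 to 3.34 ± 0.308, and Ifi44 was 5.63-fold lower. Irf7, a transcription factor of the interferon response chosen here after its values were seen, fell from 844 ± 81.5 to 230.1 ± 30.1 FPKM. Of the 20 tested members of the NF-kB and inflammatory cytokine list, 15 fell, under all 4 scalings, and 2 rose (camera adjusted p = 7.707e-12, adjusted p = 0.182 with an estimated correlation). Saa3, Lcn2, C3 and Cxcl5 led it. Against the list, Icam1, a leukocyte adhesion molecule chosen after its values were seen, rose 1.81-fold under all 4 scalings. Of 10 tested members of the antigen presentation list, 8 fell and none rose (camera adjusted p = 6.619e-06, adjusted p = 0.243 with an estimated correlation). B2m, the shared light chain of MHC class I, fell from 357 ± 5.32 to 226 ± 10.3 FPKM, and H2-K1, a class I heavy chain, from 133 ± 4.73 to 62.1 ± 6.33. Tapbp, which loads peptides on class I, was 1.95-fold lower, and Cd74, the class II invariant chain, 6.63-fold lower.

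Macrophage and monocyte markers moved with these groups, at low levels. All 16 macrophage and monocyte markers in the table had a lower mean in 3KR, with a median of 0.285 FPKM in WT and 0.0504 in 3KR. Only 2 were high enough to test, of which Mpeg1, a macrophage pore-forming protein, was the highest, at 6.79 ± 0.287 FPKM in WT and 0.854 ± 0.361 in 3KR (SD, n = 3), and was called lower. The median of the interferon list was 39.5 FPKM in WT and 11.3 in 3KR.

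Transcripts of the fibrillar matrix and of enzymes that degrade it were lower in 3KR. Of 24 tested members of the fibrillar collagen and matrix list, 18 fell, under all 4 scalings, and 5 rose, 4 of them under all 4 scalings (camera adjusted p = 1.915e-12, adjusted p = 0.182 with an estimated correlation). Col3a1, which encodes type III collagen, fell from 1424 ± 30.8 to 316 ± 14.2 FPKM (SD, n = 3). Lox, a collagen cross-linking oxidase, fell from 385 ± 15.6 to 97.6 ± 3.27, Postn, the matricellular protein periostin, from 143 ± 4.99 to 27.1 ± 2.08, and Dcn, the proteoglycan decorin, from 588 ± 16.6 to 246 ± 3.14. Col6a3, a type VI collagen chain also chosen after its values were seen, rose 1.66-fold. Of 16 tested matrix proteases and inhibitors, 10 fell and 4 rose, all 14 under all 4 scalings, while 11 fell and 4 rose adjusted over the list alone (camera adjusted p = 7.498e-06, adjusted p = 0.182 with an estimated correlation). The collagenase Mmp13 fell from 822 ± 31.1 to 136 ± 3.11 FPKM, the stromelysin Mmp3 from 489 ± 15.1 to 88.3 ± 6.30, and the elastase Mmp12 from 4.40 ± 0.154 to 0.458 ± 0.0689. Timp2, an inhibitor of such proteases, went the other way, from 1167 ± 23.3 to 2314 ± 60.2.

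The differentiation of BMSCs is named in the series title, and camera called none of its 3 marker lists. Fry tests a list without comparing it with other genes, so the shift of 0.15 of the median gene stays in its result. It called the chondrocyte list higher (fry adjusted p = 1.441e-04), the osteoblast list higher (0.00362) and the adipocyte list lower (0.0126). Of 10 tested osteoblast markers, 5 rose and 4 fell, all 9 under all 4 scalings (camera adjusted p = 0.319). The median of this list lay above the median gene (0.042) while its mean (-0.032) and the direction of the test lay below. Sp7 rose, and Col1a1, the main collagen of bone, fell from 1785 ± 50.2 to 787 ± 20.4 FPKM (SD, n = 3). Col1a2, its partner chain, fell from 881 ± 24.2 to 398 ± 14.0, and Sparc, the collagen-binding protein osteonectin, from 1868 ± 31.5 to 986 ± 8.23. Runx2, the master transcription factor of osteoblasts, Alpl, the mineralization phosphatase, and Spp1, osteopontin, were chosen after their values were seen. Runx2 rose from 11.3 ± 0.557 to 17.4 ± 0.700 FPKM, Alpl from 11.9 ± 0.457 to 15.1 ± 0.465, and Spp1 from 4743 ± 133 to 7888 ± 455. Only 10 of 17 osteoblast and 13 of 24 adipocyte markers in the table could be tested. Several markers of mature cells among the others lay near 0 in both groups. Ibsp was at 0.0543 FPKM in WT and 0.133 in 3KR, Dmp1 at 0.00639 and 0.0123, Adipoq at 0.0168 and 0.00993, and Plin1 at 0.00703 and 0.0281. Of 13 tested adipocyte markers, 6 rose, 3 of them under all 4 scalings, and 4 fell under all 4 (camera adjusted p = 0.319). Pparg, the master regulator of fat cells, rose from 1.80 ± 0.212 to 4.64 ± 0.401 FPKM, and its partner Cebpa from 13.9 ± 0.703 to 23.7 ± 2.89. Scd1, a fatty acid desaturase, rose 1.505-fold, while Lpl, lipoprotein lipase, fell from 15.3 ± 0.229 to 2.98 ± 0.309. Of 11 tested chondrocyte markers, 8 rose and 2 fell under all 4 scalings, and 8 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.319). Sox9, the cartilage transcription factor, rose from 9.95 ± 0.613 to 30.8 ± 0.439 FPKM, Col2a1, cartilage collagen, from 44.9 ± 2.63 to 115 ± 1.27, and Acan, aggrecan, from 0.529 ± 0.113 to 4.80 ± 0.142. Comp, a cartilage matrix protein, fell from 25.3 ± 1.68 to 8.82 ± 0.595.

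Markers of the stromal cells themselves were divided, and contractile transcripts rose. Of 17 tested marrow stromal markers, 8 rose, 7 of them under all 4 scalings, and 7 fell under all 4 (camera adjusted p = 0.319). Cxcl12, the chemokine that retains blood stem cells in the marrow, fell from 409 ± 8.41 to 70.3 ± 3.06 FPKM (SD, n = 3), and Ly6a, the surface marker Sca-1, from 308 ± 1.65 to 102 ± 8.25. Lepr, the leptin receptor that marks perivascular stromal cells, rose from 3.68 ± 0.258 to 16.9 ± 0.501, and Cd44, the hyaluronan receptor, from 50.2 ± 2.22 to 101 ± 1.65. All 10 tested members of the smooth muscle and myofibroblast list rose under all 4 scalings (camera adjusted p = 1.130e-04, adjusted p = 0.248 with an estimated correlation). Acta2, smooth muscle actin, rose from 123 ± 7.52 to 240.2 ± 11.9 FPKM, and Cnn1, calponin, from 1.19 ± 0.0329 to 4.53 ± 0.417. Tpm2, a tropomyosin, and Myl9, a myosin light chain, rose 2.12-fold and 2.10-fold.

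Factors by which stromal cells act on osteoclasts, the bone-resorbing cells, moved in both directions. Of 12 tested members, 5 fell under all 4 scalings and 5 rose, 3 of them under all 4 (camera adjusted p = 0.0205, adjusted p = 0.182 with an estimated correlation). Besides Cxcl12, the monocyte chemokine Ccl2 fell from 45.7 ± 0.662 to 13.9 ± 1.255 FPKM (SD, n = 3), the cytokine Il6 from 3.79 ± 0.172 to 0.887 ± 0.0621, and Il34, a ligand of the macrophage growth factor receptor, from 4.22 ± 0.256 to 1.996 ± 0.293. Tnfsf11, which encodes RANKL and was chosen after its values were seen, was at 5.60 ± 0.329 and 5.41 ± 0.313 (limma adjusted p = 0.572). The 3 members higher under all 4 scalings were also named after their values were seen. Tnfrsf11b, which encodes the RANKL decoy receptor, rose 1.265-fold (limma adjusted p = 8.813e-04), Csf1 1.32-fold and Sema3a 1.45-fold. The call of this list was lost when any of the 3 WT libraries was left out (camera adjusted p = 0.0812 without replicate 1, 0.0889 without replicate 2 and 0.0815 without replicate 3), under the 3 other scalings, and among genes at an FPKM of 5 or more (0.345). Of 5 tested osteoclast markers, 3 fell and 1 rose under all 4 scalings (camera adjusted p = 0.0192, adjusted p = 0.217 with an estimated correlation). Ctsk, cathepsin K, which stromal cells also express, fell from 209 ± 1.28 to 131 ± 3.38 FPKM, Itgb3 from 11.8 ± 0.951 to 5.30 ± 0.335, and Acp5 from 1.41 ± 0.202 to 0.781 ± 0.0633, while the transcription factor Nfatc1 rose from 6.36 ± 0.142 to 10.3 ± 0.331. The macrophage and monocyte markers, of the lineage osteoclasts come from, were lower in 3KR as given above. This call of the osteoclast list was lost after median ratio scaling (camera adjusted p = 0.109), quantile normalization (0.0646) and without a filter on low values (0.0927).

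Cell cycle transcripts were higher in 3KR. All 24 tested members of the G2 and M phase list rose under all 4 scalings, with a median relative log2 change of 0.69 (camera adjusted p = 2.132e-07, adjusted p = 0.107 with an estimated correlation). Mki67, the proliferation marker, rose from 12.5 ± 0.730 to 28.4 ± 1.98 FPKM (SD, n = 3), and Anln, Kif23 and Kif20a, which act in cell division, rose 2.50-fold, 2.47-fold and 1.98-fold. All 16 tested S phase members rose, 14 of them under all 4 scalings (camera adjusted p = 2.681e-04, adjusted p = 0.182 with an estimated correlation). Rrm2 and Rrm1, subunits of ribonucleotide reductase, rose 1.99-fold and 1.32-fold, the replication helicase subunit Mcm4 1.84-fold, and Slbp, the histone mRNA binding protein, 1.56-fold. Of 19 tested p53 targets and senescence genes, 12 rose, 9 of them under all 4 scalings, and 1 fell, while 12 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.183). Mdm2, which targets p53 for degradation, rose 1.78-fold, Gtse1 1.85-fold and Ccng1 1.52-fold, and Igfbp7 fell from 20.4 ± 0.0690 to 8.62 ± 0.765 FPKM.

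Stress and metabolic lists moved in different directions. Of 18 tested members of the unfolded protein and integrated stress response list, 12 fell under all 4 scalings, and 2 rose on the deposited scale but not under all 4 (camera adjusted p = 1.079e-07, adjusted p = 0.214 with an estimated correlation). The leading members act in amino acid supply and its control. Asns, asparagine synthetase, fell from 50.5 ± 1.49 to 28.9 ± 1.11 FPKM (SD, n = 3), Psat1, of serine synthesis, from 126 ± 4.38 to 71.9 ± 3.38, Mthfd2, of mitochondrial folate metabolism, from 72.9 ± 2.44 to 40.2 ± 1.82, and the pseudokinase Trib3 from 24.2 ± 0.590 to 7.60 ± 0.329. The chaperones Hspa5 and Hsp90b1, chosen after their values were seen, had log2 differences of 0.064 and 0.058 as deposited, with limma adjusted p of 0.134 and 0.170. Other members, also chosen after their values were seen, went either way on the deposited scale, where the median gene was 0.15 higher. Herpud1 was at 31.83 to 34.02 FPKM in WT and 26.02 to 29.39 in 3KR, and Xbp1 at 11.18 to 11.75 and 9.834 to 10.31. Pdia4 was higher as deposited, at 225.4 to 234.7 FPKM in WT and 249.1 to 264.5 in 3KR, but was not called higher under all 4 scalings. Of 16 tested hypoxia and glycolysis members, 11 fell under all 4 scalings and 3 rose, 1 of them under all 4 (camera adjusted p = 2.258e-07, adjusted p = 0.182 with an estimated correlation). P4ha1, a collagen prolyl hydroxylase subunit, fell from 181 ± 4.47 to 80.9 ± 3.40 FPKM, Pdk1, a pyruvate dehydrogenase kinase, from 13.9 ± 0.138 to 5.10 ± 0.329, and Ndrg1 and Adm were 1.77-fold and 1.68-fold lower. Of 14 tested NRF2 targets, which act against oxidants, 10 rose, 9 of them under all 4 scalings, and 2 fell (camera adjusted p = 0.0898). Hmox1, haem oxygenase 1, rose from 89.1 ± 2.76 to 213 ± 15.0 FPKM, Nqo1 from 2.10 ± 0.184 to 7.30 ± 0.637, Gclc 2.48-fold and Abcc1 1.67-fold. The NRF2 list was called higher under each of the 3 other scalings (camera adjusted p from 0.007945 to 0.0352), with an adjusted p of 0.440 with an estimated correlation as deposited. Of 12 tested heat shock genes, 7 were higher, 3 of them under all 4 scalings (camera adjusted p = 0.188), led by Hspb1 at 2.05-fold and Cryab at 1.39-fold. Of 20 tested nuclear genes of oxidative phosphorylation, 13 were higher, but only 2 of them under all 4 scalings, and 1 was lower (camera adjusted p = 0.260). Atp5b and Uqcrc1 were 1.23-fold higher on the deposited scale. None of 26 ribosomal protein genes passed limma's test, and Rps25, at 121 ± 4.503 and 136 ± 12.8 FPKM, came nearest with an adjusted p of 0.0574. The ribosomal list was not called as deposited (camera adjusted p = 0.156) but was called lower after rescaling to the same sum (0.0190), after median ratio scaling (0.00237), without WT replicate 1 (0.0340) and without 3KR replicate 3 (0.0183), with an adjusted p of 0.760 with an estimated correlation as deposited. Its members Rpl32 and Rpl23 were called lower under each of the 3 other scalings. Of 19 tested genes of the cholesterol synthesis list, 7 were higher, 3 of them under all 4 scalings, and 5 were lower, against 8 and 5 adjusted over the list alone (camera adjusted p = 0.495). Stard4, a sterol carrier, was 1.34-fold lower, while Idi1, an isomerase of isoprenoid synthesis, was 1.36-fold higher.

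Signalling lists held changes of both signs and were not called by camera, while fry called Wnt (adjusted p = 0.00653), BMP and TGF-beta (8.522e-05) and Notch and Hedgehog (0.00594). Of 16 tested Wnt targets and ligands, 7 rose and 5 fell, all 12 under all 4 scalings (camera adjusted p = 0.589). The median of this list was 0.0021 and its mean -0.13 relative to the median gene, and the test pointed down. The list mixes targets with ligands, receptors and inhibitors, so its counts do not give a direction of Wnt output. Axin2 and Tcf7, targets chosen after their values were seen, were higher in 3KR. Axin2 was at 4.174 to 4.543 FPKM in WT and 7.455 to 7.661 in 3KR, and Tcf7 at 1.052 to 1.265 and 2.422 to 2.974. Lgr5, in the same list, fell as given above. Ccnd1, cyclin D1, rose from 96.8 ± 1.43 to 288 ± 11.03 FPKM (SD, n = 3), and Sfrp2 and Sfrp1, secreted Wnt inhibitors, fell from 117 ± 5.51 to 14.6 ± 1.247 and from 168 ± 5.52 to 41.3 ± 4.17. All 22 tested members of the BMP and TGF-beta list differed, of which 14 rose, 11 of them under all 4 scalings, and 8 fell under all 4 (camera adjusted p = 0.860). Id2 rose from 11.2 ± 0.393 to 37.5 ± 2.01 FPKM and Ltbp1, which tethers latent TGF-beta, from 19.1 ± 0.681 to 48.5 ± 1.42, while the ligand Bmp4 fell from 63.5 ± 0.650 to 16.1 ± 1.92. Of 8 tested Notch and Hedgehog genes, 4 rose and 1 fell under all 4 scalings, against 4 and 2 adjusted over the list alone (camera adjusted p = 0.925). The receptor Notch1 rose 1.75-fold and Notch3 1.30-fold, Hes1, a Notch target, rose from 0.911 ± 0.107 to 1.82 ± 0.183 FPKM, and Notch2 was 1.42-fold lower. Of 14 tested immediate early genes, 3 rose and 4 fell under all 4 scalings (camera adjusted p = 0.319). Fosl1 and Dusp1 rose 2.26-fold and 1.81-fold, Ier3 rose 1.28-fold, and Egr1 was 1.32-fold lower.

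Camera called none of the lists of m6A writers, m6A erasers and readers, and SUMO pathway genes, while fry called all 3 higher on the deposited scale (adjusted p = 0.00630, 5.596e-05 and 6.027e-04). Of 7 tested m6A writer genes, 3 were higher on the deposited scale, of which only Zc3h13, at 11.2 ± 0.0517 and 14.6 ± 0.324 FPKM (SD, n = 3), was called under all 4 scalings. Adjusted over the list alone, 2 were higher (camera adjusted p = 0.495). The median of the writers was -0.0019 and their mean 0.044 relative to the median gene. Rbm15, of the writer complex, was at 4.67 ± 0.565 and 6.69 ± 0.885 FPKM, and lost its call after median ratio scaling. The catalytic subunit Mettl3, at 18.2 ± 2.09 and 20.9 ± 0.409, had a limma adjusted p of 0.0472 that lay above 0.05 under each of the 3 other scalings, and its partner Mettl14 was at 13.8 ± 1.15 and 15.0 ± 0.408 (limma adjusted p = 0.124). Of 13 tested erasers and readers, 10 were higher, 3 of them under all 4 scalings, and 2 were lower, against 11 and 2 adjusted over the list alone (camera adjusted p = 0.260). Besides Fto, the readers Hnrnpa2b1 and Igf2bp2 were 1.29-fold and 1.27-fold higher under all 4 scalings, while Ythdf3, 1.22-fold higher as deposited, was not called after median ratio scaling. Of 19 tested SUMO pathway genes, 12 were higher and none lower, but only 3 of the 12 under all 4 scalings (camera adjusted p = 0.220, and 0.0204 without a filter on low values). These were the SUMO ligases Pias3 (1.42-fold) and Ranbp2 (1.33-fold) and Sae1, a subunit of the SUMO-activating enzyme (1.35-fold). Pias2, 1.20-fold higher as deposited, lost its call after median ratio scaling.

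The 7 other lists had too few tested members, and their levels are given without a list test. Of 6 granulocyte markers in the table, 5 had a lower mean in 3KR, as the inflammatory lists did, and the only one tested, the neutrophil collagenase Mmp8, fell from 1.73 ± 0.324 to 0.198 ± 0.0374 FPKM (SD, n = 3). The median level of the granulocyte markers was 0.0824 FPKM in WT and 0.0535 in 3KR, that of the lymphocyte markers 0.0022 and 0.0193, that of the erythroid and megakaryocyte markers 0.108 and 0.0461, and that of the endothelial markers 0.0545 and 0.0462. Of the endothelial genes only Tek was tested, at 5.13 ± 0.531 FPKM in WT and 1.46 ± 0.0818 in 3KR (SD, n = 3). Of 5 replication-dependent histone genes in the table, 3 were tested, of which 2 were higher and Hist1h1c was lower, at 215 ± 4.13 and 132 ± 4.99 FPKM. The mitochondrially encoded list had 1 gene in the table, mt-Nd6, at 4.92 FPKM in WT and 5.45 in 3KR, and its other members were not analysed here.

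**Figure D2:**
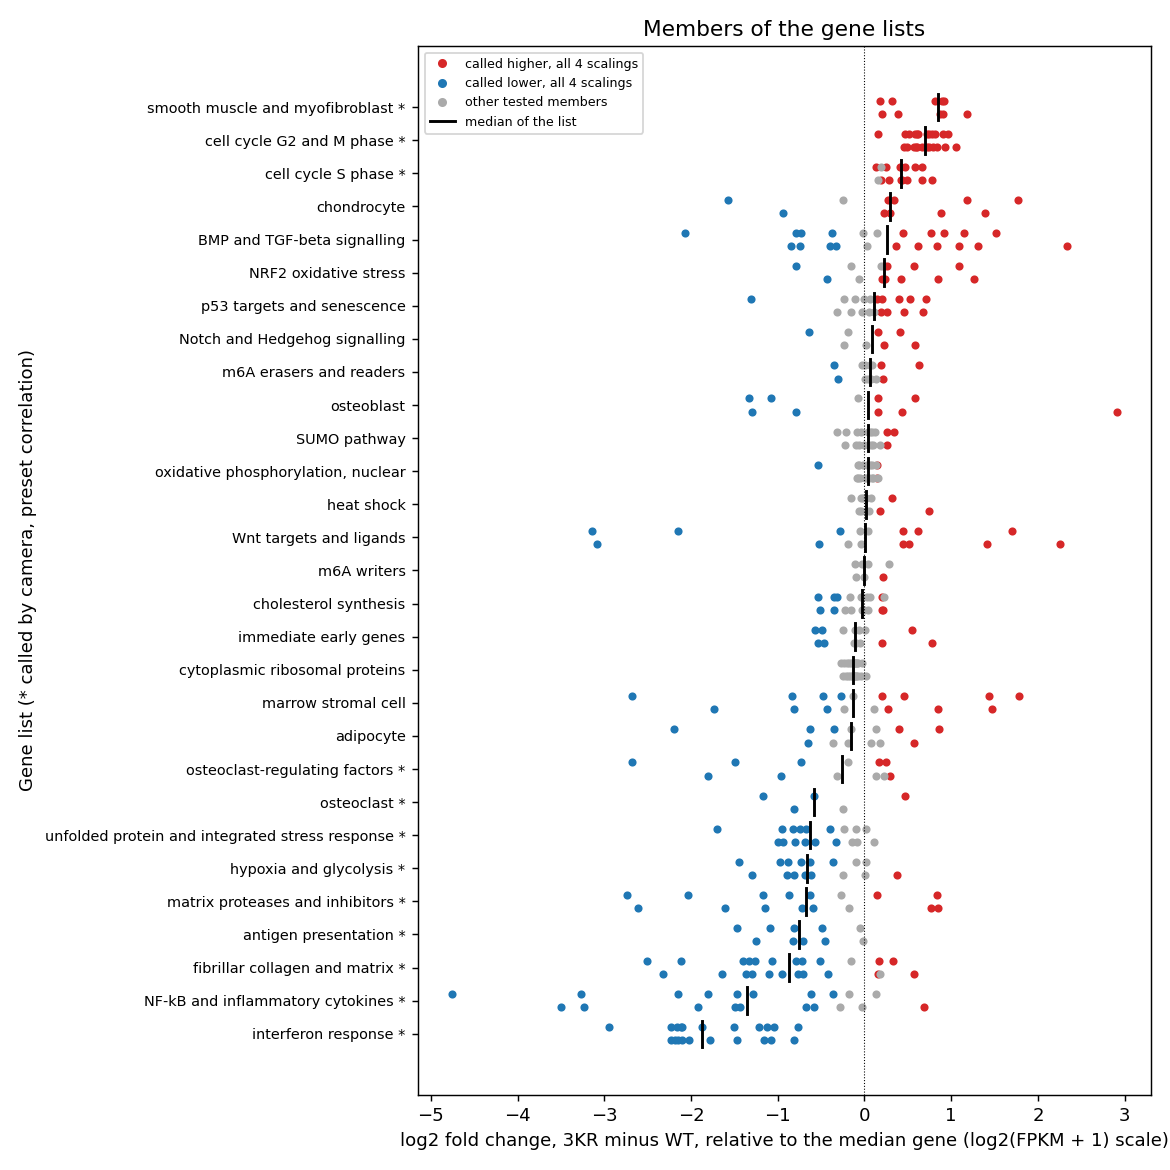
Log2 fold change of each tested list member, 3KR minus WT, relative to the median gene (horizontal axis, log2(FPKM + 1) scale), for the 29 tested lists. Points are coloured by their call under all 4 scalings, black lines are list medians, and asterisks mark the 12 lists that camera called with its preset correlation. The interferon list has the lowest median, -1.87, and the smooth muscle and myofibroblast list the highest, 0.85.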

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

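The tests of a minimum fold of 1.5 were chosen after seeing the data, and the other alternatives before. Of 132 named genes, 113 were tested in every alternative. Where tested, 129 kept one direction, and of the 127 called, 120 kept their call and direction. Of the 12 called lists, 10 kept call and direction, where tested, under the 15 alternatives other than an estimated correlation and fry. Fto was called higher in each fit. The depth is unknown. Changes of 1.1-fold were mostly missed in simulated data, but with 200 changed genes per run the adjustment there was stricter than in the data.

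The 6662 genes changed became 5016 after median ratio scaling, with 2371 higher and 2645 lower, and 3142 were higher after quantile normalization. At a pseudocount of 0.1, 339 genes were at least 2-fold higher and 383 lower, since it shrinks low genes less. A minimum fold of 1.5 left 640 genes (260 higher and 380 lower), and 682 (174 higher and 508 lower) with median ratio scaling. Leaving out 1 library gave between 5638 and 6466 genes. The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at -0.0147, 0.0295 and -0.0338, and not every library correlated best with its own number. With the number as a block, 6425 genes were called.

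Without a filter 18 lists were called, among them SUMO pathway (camera adjusted p = 0.0204), p53 (0.0212), NRF2 (0.0130), heat shock (0.0255) and oxidative phosphorylation (0.0383), all higher. The 18 include lists that had too few tested members in the main fit, whose results without a filter are not given here. Oxidative phosphorylation was also called without 3KR replicate 1 (0.0399). With an estimated correlation 0 lists were called, and by fry, which tests a list on its own without comparing it with other genes, 27. It called the adipocyte list lower (median -0.16), and the cause was not tested. It does not subtract the shift of all genes and pointed up for 6 lists that camera pointed down, whose medians relative to the median gene were 0.042 (osteoblast), -0.13 (marrow stromal), 0.0021 (Wnt), -0.027 (cholesterol), -0.13 (ribosomal) and -0.11 (immediate early). For the other reversals the cause was not tested, and camera called none of these lists as deposited. Without a filter the Notch and Hedgehog list pointed down (median -0.032). At an FPKM of 5 or more, with fewer genes tested, the chondrocyte (0.22), BMP and TGF-beta (0.029) and Notch and Hedgehog (-0.021) lists did. The Wnt list pointed up after median ratio scaling (0.013) and quantile normalization (-0.017). Mettl14 (-0.037), Rps25 (-0.0048) and Rps2 (-0.042) turned negative under median ratio scaling, which removes the shift. Leaving out 1 library at a time turned the test in 1 of 6 cases for Notch and Hedgehog (medians 0.054 to 0.118), in 3 of 6 for BMP and TGF-beta (-0.028 to 0.42) and in 1 of 6 for ribosomal proteins (-0.17 to -0.063).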

Other observations

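The tests of the interferon pattern and of a bias with expression level were chosen after the results were seen. The members of the 3 added lists below were written down after the leading genes had been seen but before the members were tested, and the counts of the fixed BMP and TGF-beta list were known by then. The tests on members in no fixed list, and without C1qtnf1, were chosen after the results were seen.

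Further groups were tested from hypotheses formed on genes seen to differ. The first was that 3KR cells carry more BMP-SMAD output, since Id1, Id2, Id3 and Atoh8 were higher. Of 10 other targets tested, 9 rose under all 4 scalings, at percentile 100 of 10000 random lists matched on expression, but 5 of the 10 were in the fixed BMP and TGF-beta list. Of the 5 in no fixed list, 4 rose under all 4 scalings, with a median relative log2 change of 0.54 at percentile 99.93. Nog, Smad9, Bambi and Gata3 had WT means under 1 FPKM and passed the filter through their 3KR level. A target as low that did not rise could not be tested, so the share that rose is partly set by the filter. Msx2, a bone homeobox gene, rose from 91.0 ± 3.39 to 164 ± 1.41 FPKM (SD, n = 3) and Gata3, a transcription factor, from 0.794 ± 0.262 to 2.39 ± 0.153, while Msx1 was not called. Higher BMP-SMAD output may thus be present, although Bmp4 itself fell. The hypothesis of more ERK and FGF output, from Fgfr3, Etv4, Etv5 and Ccnd1, gave percentile 99.7, and 99.04 for the 14 members in no fixed list, of which 8 rose, 7 of them under all 4 scalings, and 3 fell. Dusp6, an ERK phosphatase, rose from 37.9 ± 3.53 to 69.8 ± 3.09 FPKM and Spred2 from 12.1 ± 0.903 to 23.5 ± 0.650, while Spry1 fell from 3.92 ± 0.327 to 1.27 ± 0.0575, so the members were not of 1 direction. For lower complement beyond C3 and Cfb, the list first written gave percentile 0.03 but held C1qtnf1, an adipokine that is not a complement component. Without it only 3 components could be tested, too few to weigh. C2 and Serping1 fell, Serping1 from 25.4 ± 0.509 to 6.01 ± 0.458 FPKM, and Masp1 rose. These percentiles describe these libraries, since genes are not independent replicates.

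Interferon and inflammatory transcripts fell together in 3KR, and all 35 members of both lists called lower stayed so under all 4 scalings, but the 3 other scalings lower 3KR, so this was bound to hold and decides nothing. The scaling of the libraries is argued against by size instead, since 1 factor per library moves all genes alike, while the list medians were -1.72 (interferon) and -1.21 (NF-kB) as deposited and the median gene 0.15. That macrophages in the WT cultures themselves carried the interferon transcripts is argued against by levels. The median loss over 16 macrophage markers was 0.0113 of that over the interferon list. The highest marker, Mpeg1 at 6.79 FPKM in WT, lay far below the interferon median of 39.5. This comparison does not cover the NF-kB list, and it cannot decide whether macrophages acted on the other cells. All 16 markers were lower in 3KR, so fewer macrophages there stay possible. A different level of Fto cannot be told apart from the 3KR form, as its transcript was 1.71-fold higher in 3KR and no library has the level matched. A different innate response to the virus preparations or a different culture state stays open and untested, as does an effect of the form itself.

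The median gene was higher in 3KR. A different share of the 10 most abundant genes is argued against, since they took 19.2% to 19.4% of the sum in 3KR and 16.4% to 16.6% in WT, and a larger share lowers the other genes. Rescaled to the sum without them, the shift was 0.12 (standard error 0.0055), against 0.15 as deposited and 0.086 when rescaled to the sum of all genes. A bias with expression level is argued against too, because the medians of the 10 level groups lay within 0.0284 of the median of all genes. The shift goes with a larger sum of FPKM in 3KR, and how the submitters normalized, including which lengths and totals they used, stays open.

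The number of genes changed was compared between splits of the 6 libraries into 3 and 3. With 10 splits the share with as large a result cannot go under 0.1, and 1 of the 10, the real one, reached the 6662 genes, while the highest other split called 1. For lists, camera with its preset correlation called 12 in the real split and between 8 and 12 in each of the 9 mixed ones, so 2 splits, the real one included, reached 12, and the list calls alone do not separate the real grouping from mixed ones. Each mixed split keeps part of the difference between the groups, so it is not a reference without change. In the gene test the difference also adds to the spread within the mixed groups. Few genes called there were thus bound to follow, and the contrast of 6662 with 1 decides nothing. Cells from mice of different sex in the groups cannot be told apart, since Xist was at 0.111 ± 0.0510 FPKM in WT and 0.0282 ± 0.0489 in 3KR (SD, n = 3, a ratio of 0.254), too low in both to decide, and the Y-linked genes sought were not analysed here.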
